A study of Arabidopsis thaliana
Trichoderma atroviride and Arabidopsis thaliana with 10 samples.

How the data were processed

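Small RNA libraries were made from roots of Arabidopsis thaliana, ecotype Col-0, grown without the fungus or together with Trichoderma atroviride, a soil fungus used as a plant growth promoter and biocontrol agent. The 10 libraries fell into 5 groups of 2: uninoculated roots at 0 h, and root material from the contact zone after 24, 48, 72 and 96 h of co-culture. Groups and replicate numbers were taken from the sample titles. The labels did not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The only controls were taken at 0 h, so co-culture and time in culture were not separable in any comparison with them.

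The authors deposited raw read counts per distinct sequence and library, not normalized, per the file headers. The deposited sequence length in nt is another column of the same table. Cutadapt 1.9.1, Trimmomatic 0.36 and the build TAIR10 were named in the submitters' processing notes, with no role or order. An aligner, a read filter and the rule that chose the sequences are not given in the sources used here. The table may therefore hold part of each library, and its totals are totals of the table and not sequencing depths. No assignment of sequences to plant or fungus was given in the table, and no T. atroviride genome was used here.

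The table held 68794 sequences of 18 to 25 nt. Totals per library ran from 19047 to 833922 counts, a 43.8-fold range, and 51570 sequences occurred in 1 library only while 254 occurred in all 10. Each sequence was searched over its full length, without mismatch, on both strands of the TAIR10.1 assembly with its plastid and mitochondrial chromosomes. Sequences with at least 1 match are called matched and the rest unmatched. An exact match does not show plant origin for conserved RNA such as rRNA, and an unmatched sequence can be fungal, bacterial, a plant sequence with an error, or spliced plant RNA. Unmatched sequences were also searched with 1 mismatch allowed (bwa 0.7.19, no gaps) and, without gaps, with up to 4 mismatches against the Arabidopsis rRNA genes, beside base-shuffled copies of themselves. They are named by their row in the table and are not printed.

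Matched sequences were given 1 class each from the TAIR10.1 annotation, structural RNA first. The order began with rRNA, tRNA, snoRNA or snRNA, mature miRNA, miRNA precursor and TAS. Other organelle RNA, coding gene in sense or antisense, pseudogene, other non-coding gene and intergenic came after these. A 45S unit was taken as 5800 nt at each long nuclear rRNA gene. The profile along the unit and the search for near matches used the copy on chromosome 2. A transposable element annotation was not used here. Coordinates are 1-based TAIR10.1 positions. A sequence with several places was counted once and is uncertain as to its source. This holds for all 45S rRNA fragments, the 4 tested snoRNA fragments and most tRNA fragments.

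Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr, R 4.3.3) in 1 fit of all 10 libraries with 5 residual degrees of freedom. Matched sequences, unmatched sequences and class sums were scaled and tested separately, and calls needed a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each co-culture time, the mean of the 4 times and any time against the control, and 24 to 48, 48 to 72, 72 to 96 and 24 to 96 h. The SE printed with an edgeR log2 fold change is the size of that change divided by the square root of its F statistic. It therefore restates the test and is no separate measure of precision. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside edgeR. With 2 against 2 libraries an exact permutation test of a single value cannot go below p = 0.333, so shares are given with their SD (n = 2) and no permutation test. No comparison had 3 libraries on both sides.

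Of the 20 lists of miRNAs, genes and RNA kinds that were fixed, 2 had at least 3 tested sequences and were tested with camera (limma, preset correlation 0.01), with an estimated correlation and with fry; for the rest counts are given. The list of unmatched sequences was tested sequence by sequence as a set of its own. miRNA families were read from annotated mature miRNAs and from 65 mature sequences written down in advance. The features to be named were the called ones with the largest changes, the most abundant called ones, up to 4 tested members of each list, the 10 most abundant unmatched sequences and PRIM2. Since no sequence was called by edgeR, only the list members, the unmatched sequences and PRIM2 were named by that rule. Any other sequence or locus in the text was chosen after its values were seen.

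Shares of single libraries carry 95% Wilson intervals, and a count of 0 allows up to 3 counts. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. Duplicate libraries were looked for with a chi-square test of the counts of each replicate pair. Its statistic was at least 6.67 per degree of freedom, so no pair was counted as 1 library.

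The fitting code was tested on simulated counts for the 492 tested matched sequences, with 200 of them changed by known folds. With the spread estimated from the libraries (common dispersion 1.87) it recovered 0 of 100 changes of 4-fold and 0 of 100 of 16-fold in each of the 4 comparisons with the control. With a dispersion of 0.05 it recovered 81, 73, 74 and 73% of the 4-fold and 93, 92, 99 and 94% of the 16-fold changes at 24, 48, 72 and 96 h, with 1, 3, 7 and 5 false calls. Alternatives changed the scaling, the tool, the filter, the libraries in the fit, the replicate block, the mismatch rule, the RNA kinds included and the counting of copies; their effect is given at the end.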

Results

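The series asked how the small RNA population of Arabidopsis roots looks during the first days of contact with T. atroviride, and its title names a fungal small RNA directed at PRIM2, the gene of the large primase subunit, which helps start DNA synthesis. Counts per sequence were compared between 2 uninoculated libraries at 0 h and 2 libraries at each of 24, 48, 72 and 96 h of co-culture. The control libraries held 36106 and 195390 counts. The co-culture libraries, replicate 1 before replicate 2, held 77778 and 32566 counts at 24 h, 833922 and 30557 at 48 h, 187255 and 19047 at 72 h, and 52152 and 234454 at 96 h.

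The counts came mainly from rRNA and from sequence without an exact place in the Arabidopsis genome. Among distinct matched sequences nuclear rRNA, with 3652, came after sense fragments of coding genes (11868) and intergenic sequence (4169). Of the 68794 sequences, 27193 (39.5%) matched the genome exactly. Matched sequences held 13.7% ± 4.38 (SD, n = 2) of the counts in the uninoculated roots, 48.3% ± 13.3 at 24 h, 42.2% ± 33.6 at 48 h, 75.8% ± 19.7 at 72 h and 14.0% ± 4.65 at 96 h. At 48 h the libraries lay apart, at 18.5% (95% Wilson interval 18.4 to 18.5) and 66.0% (65.4 to 66.5). All libraries of 24, 48 and 72 h lay above both controls, 48 h replicate 1 by little. The 96 h libraries, at 17.3% and 10.7%, overlapped the controls, at 10.6% and 16.8%. The Wilson intervals of the controls were 10.3 to 10.9% and 16.7 to 17.0%. No test was made of these shares. Unmatched sequences thus held 86.3% ± 4.38 of the counts of roots that had met no fungus.

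**Figure D1:**
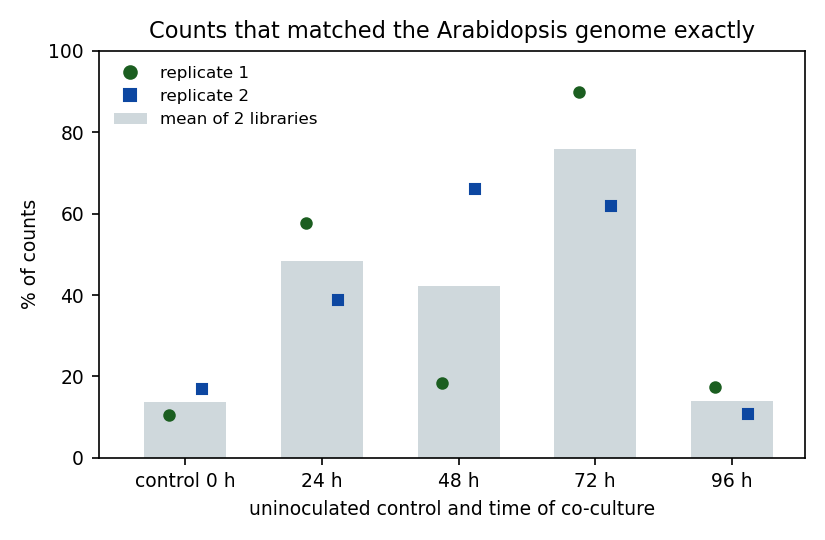
Percent of the counts of each library (y axis) in sequences that matched the Arabidopsis genome exactly, for the uninoculated control and 4 times of co-culture (x axis). Circles are replicate 1, squares replicate 2 and bars the mean of 2 libraries; the controls (10.6 and 16.8%) and the 96 h libraries (17.3 and 10.7%) lie low, and the 48 h libraries (18.5 and 66.0%) lie apart.

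As a mean of the 10 libraries, nuclear rRNA made up 63.4% of matched counts (45.7 to 75.5%), coding genes in sense 12.9995% (7.67 to 20.7%) and nuclear tRNA 8.98% (4.86 to 12.2%). Intergenic sequence made up 5.30% (1.02 to 11.6%) and coding genes in antisense 4.57% (0.610 to 9.97%). The order differed between libraries: nuclear tRNA lay above sense fragments of coding genes in 3 of them, both controls and 96 h replicate 1, and above intergenic sequence in 7. Along the 45S unit (chromosome 2, 3706 to 9505) 99.7% of the counts were in sense. The interval 8706 to 8805, held 35.1% of the nuclear rRNA counts as a mean of 10 libraries, and 8506 to 8605 held 15.7%. The most abundant matched sequence, ACGGGCTTGGCAGAATCAGCGGGG (chromosome 2, 8507 to 8530), took 4.38% of the matched counts as a mean over libraries. Among nuclear tRNAs, tRNA-Ala supplied 45.7% of the counts as a mean of 10 libraries and tRNA-Glu 19.6%. The share of tRNA-Ala ran from 13.005% in 96 h replicate 1 to 80.2% in control replicate 2 and was the highest in 7 libraries. In 48 h replicate 2 and 72 h replicate 2 tRNA-Glu had the highest share, and in 96 h replicate 1 tRNA-Pro. The 5' tRNA-Ala fragment GGGGATGTAGCTCAGATGGTAGAG matched 15 places, the first on chromosome 1 at 2025356 to 2025379.

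**Figure D2:**
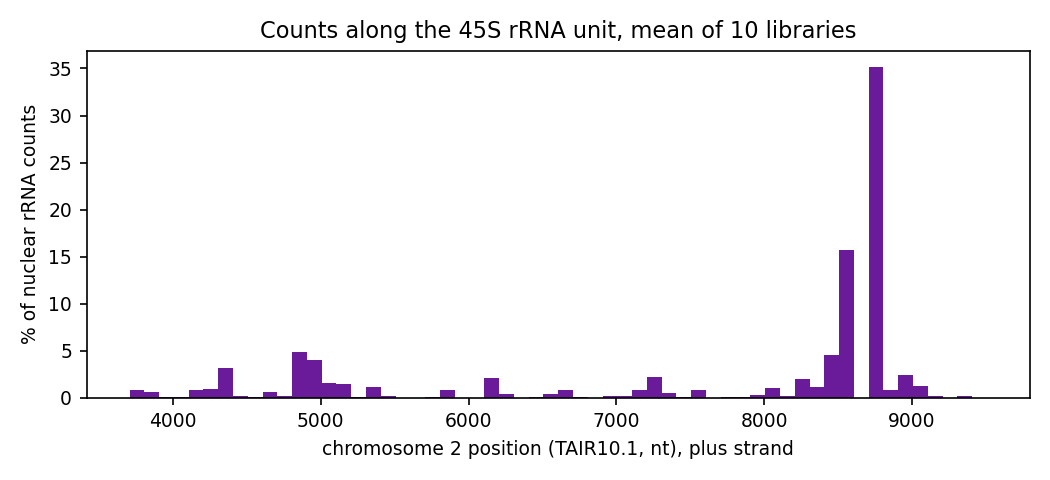
Percent of nuclear rRNA counts (y axis, mean of 10 libraries) in windows of 100 nt along the 45S unit on the plus strand of chromosome 2 (x axis, TAIR10.1 position in nt). Each bar is 1 window; the tallest, at 8706 to 8805, holds 35.1% of the counts.

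**Figure D3:**
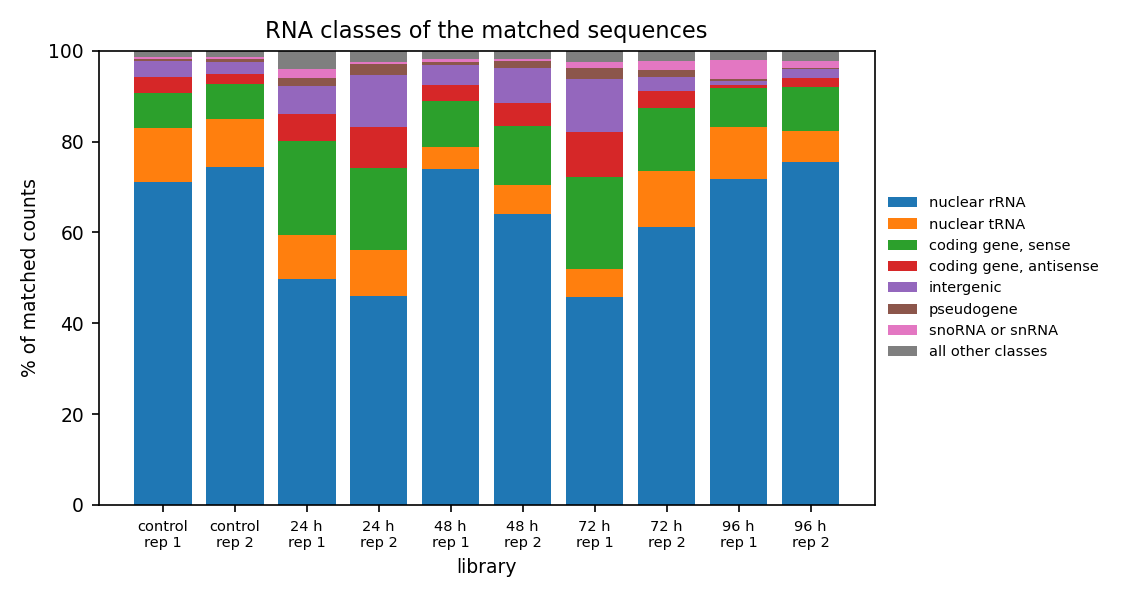
RNA classes as percent of matched counts (y axis) in each of the 10 libraries (x axis). Colours mark the classes; nuclear rRNA, at the bottom of each bar, ranges from 45.7% (72 h replicate 1) to 75.5% (96 h replicate 2).

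Known plant small RNAs were scarce. Mature miRNAs of 32 annotated names held 1268 counts, a mean of 0.204% of the matched counts of a library, and 8 of the 65 mature sequences written down in advance occurred. Single libraries decided many of these counts, so counts without the largest library are given too. The most abundant name, miR8175, belongs to none of the lists and held 383 counts, 207 without 24 h replicate 1. The family group that feeds back on the silencing machinery (miR162, miR168, miR403) held 410 counts (252 without 48 h replicate 1), of which 350 were miR403-3p, the regulator of AGO2 (237 without 48 h replicate 1). The copper group (miR397, miR398, miR408, miR857) held 121 counts and 38 without 48 h replicate 1. The same library supplied most counts of the growth and phase change group, such as miR156 (82, 19 without it), the defence group (25, 8 without it) and the triggers of secondary siRNAs (24, 7 without it). It also held 17 of the 34 counts of the auxin group. In the auxin, defence and trigger groups its 17 counts were the same ones, those of miR393, which all of these groups include. The 3 counts of the sulfate group (miR395) lay in control replicate 2. The phosphate starvation group (miR399, miR827, miR2111) had 0 counts, which allows up to 0.0782% of the matched counts in the smallest control library and 0.00178% in the 72 h replicate 1 library. TAS loci held 74 counts, 19 without 24 h replicate 1, and the PPR genes that give phased siRNAs 67, 39 without that library. The auxin receptor genes had 3 counts, all in 72 h replicate 1, and the defence genes 27, 9 without that library. Of the 673 counts on genes of the silencing machinery (416 without 96 h replicate 2), 672 lay on AGO2. Plastid-encoded RNA, a marker of shoot tissue, held 1134 counts and mitochondrial RNA 3959, with 788 and 2711 without 72 h replicate 1. Structural tRNA and rRNA fragments held 327045 counts, 204502 without 48 h replicate 1, and snoRNA and snRNA fragments 5160, 3185 without 72 h replicate 1. The unmatched sequences, which include any from T. atroviride, held 1216892 counts and 536960 without 48 h replicate 1. The transposable element list was not analysed here.

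PRIM2 (AT1G67320, named EMB2813 in the annotation; chromosome 1, 25205279 to 25209101, minus strand, 18 exons) had 0 matching sequences in the table, on either strand. The other primase and polymerase alpha genes gave 25 counts, all on POLA1 (AT5G67100), with 8 left without 72 h replicate 1.

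At 24 h of co-culture nuclear rRNA fragments made up 47.9% ± 2.67 (SD, n = 2) of matched counts against 72.8% ± 2.32 in uninoculated roots. Over all counts the direction was the opposite, 23.3% ± 7.66 against 10.04% ± 3.51, since the matched share itself was higher at 24 h. Of matched counts, sense fragments of coding genes made up 19.5% ± 1.77 against 7.74% ± 0.110, antisense fragments 7.47% ± 2.21 against 2.87% ± 0.844, and intergenic sequences, where siRNAs of 24 nt are commonly made, 8.75% ± 3.52 against 3.04% ± 0.570. None of 15 classes passed the edgeR test at 24 h, with 0 at an unadjusted p under 0.05, and limma-voom called 0 with 1. The log2 fold change of nuclear rRNA was -1.22 (SE 0.65) with an edgeR adjusted p of 0.477, while DESeq2 called this class alone, with an adjusted p of 0.00729 and 2 classes at an unadjusted p under 0.05. The 394 tested tRNA and rRNA fragments were most of the 492 tested sequences, so camera compared this list with a minority. Many of them overlap, such as those from 8507 to 8530 and from 8508 to 8531 on chromosome 2, and are not independent. With the preset correlation of 0.01 the p-values of this list can therefore be too small in every comparison. As a list the 394 fragments ranked below the other sequences at 24 h (camera, adjusted p = 7.28e-08; adjusted p = 0.0334 with an estimated correlation), with a median log2 fold change of -0.29. This list call was lost without 24 h replicate 2 (adjusted p = 0.123). None of the 492 tested matched sequences was called by edgeR, 3 had an unadjusted p under 0.05 and 24.6 would by chance, and DESeq2 and limma-voom called 0, with 16 and 13 at that level. Adjusted over the list alone, 0 of the 394 fragments were called. The 4 tested snoRNA fragments all had positive log2 fold changes, with a median of 1.71, and did not pass the list test (adjusted p = 0.168). The 45S fragment CGGGCTTGGCAGAATCAGCGGGGA (chromosome 2, 8508 to 8531) had a log2 fold change of -1.10 (SE 1.39). miR403-3p (TTAGATTCACGCACAAACTCG, chromosome 2, 19415154 to 19415174, in MIR403) had 0.66 (SE 2.36), and between 0.12 and 0.89 at the other times. This sequence had 0 counts in 1 library of every group, so these folds rest on single libraries and show no shared rise.

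At 48 h the rRNA share was 69.0% ± 7.08 of the matched counts against 72.8% ± 2.32 in uninoculated roots, and nuclear tRNA made up 5.64% ± 1.10 against 11.2% ± 0.832. Over all counts the 48 h libraries lay apart, with 13.7% and 42.3% nuclear rRNA against 7.56% and 12.5% in the controls, and 0.898% and 4.23% nuclear tRNA against 1.25% and 1.78%. Antisense fragments of coding genes made up 4.32% of matched counts and intergenic sequences 5.997% ± 2.36. The most abundant 45S fragments, from 8507 to 8530 and from 8736 to 8759 (GGTGGGGAGTTTGGCTGGGGCGGC), had log2 fold changes of 0.18 (SE 1.27) and -0.34 (SE 1.39). The structural list ranked lower by camera (adjusted p = 0.0240), although its median log2 fold change was positive, 0.38, and the call was lost with an estimated correlation (adjusted p = 0.345). It was also lost without control replicate 2 (adjusted p = 0.208) and without 48 h replicate 2 (adjusted p = 0.885). edgeR called 0 of 492 sequences and 0 classes, with 5 and 0 at an unadjusted p under 0.05. DESeq2 and limma-voom called 0 sequences, with 5 and 11 at that level, and 0 classes, with 1 and 0. Adjusted over the list alone the structural and the snoRNA list gave 0 calls each.

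At 72 h nuclear rRNA made up 53.5% ± 10.99 of matched counts, sense fragments of coding genes 17.1% ± 4.57, antisense fragments 6.88% ± 4.36 and snoRNA and snRNA 1.60% ± 0.597. Over all counts nuclear rRNA made up 39.5% ± 2.21, above the 10.04% ± 3.51 of uninoculated roots. The 45S fragment TGTCAGGTGGGGAGTTTGGCTGGG (chromosome 2, 8731 to 8754) had a log2 fold change of -4.12 (SE 1.57), with an edgeR adjusted p of 0.919. The fragment from 8507 to 8530 had a log2 fold change of 2.04 (SE 1.32), and 24948 of its counts lay in 72 h replicate 1. A fragment of the mitochondrial 18S rRNA gene rrn18 (TTGAGTGAGACAGAGGAGAG, mitochondrial chromosome, 127557 to 127576) had a log2 fold change of -3.05 (SE 2.21). The structural list ranked lower by camera (adjusted p = 0.00495) with a positive median of 0.12, and the call was lost with an estimated correlation (adjusted p = 0.226). Without control replicate 2 the adjusted p was 0.0671, and without 72 h replicate 1 it was 0.775 with the opposite sign. edgeR called 0 of 492 sequences with 14 at an unadjusted p under 0.05, DESeq2 0 with 53 and limma-voom 0 with 11. Adjusted over the list alone the structural and snoRNA lists gave 0 calls. DESeq2 called nuclear rRNA with a log2 fold change of -1.28 (adjusted p = 0.0208), with 2 classes at an unadjusted p under 0.05, while edgeR and limma-voom called 0 classes, with 0 and 1.

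At 96 h nuclear rRNA made up 73.7% ± 2.56 of matched counts and 10.3% ± 3.06 of all counts, near the uninoculated shares, while snoRNA and snRNA fragments, which come from the RNAs that guide rRNA modification and splicing, made up 2.88% ± 1.97 of matched counts against 0.436% ± 0.175. Their class fold was 2.39 on the log2 scale (SE 0.82), with an edgeR adjusted p of 0.0704 and a DESeq2 adjusted p of 0.00408. The 4 tested snoRNA fragments ranked higher as a list (camera, adjusted p = 0.00118; adjusted p = 0.0831 with an estimated correlation), with a median log2 fold change of 4.57. They were 2 fragments of U3 snoRNA genes such as U3B, GTCGCACGGCGGTCTGACAGGT with 4.10 (SE 2.60) and TGGTCGCACGGCGGTCTGACAGGT with -0.95 (SE 2.36), both ending at 21888509 on chromosome 5. The other fragments came from AT1G06247 and AT1G06277, both annotated as U51 snoRNA: CACCATCTTTCGGCTGAGATT (chromosome 1, 10300812 to 10300832) with 5.04 (SE 2.77), and the same sequence with 1 more base at its start with 8.81 (SE 4.10). None passed by itself. The 4 fragments form 2 overlapping pairs and are not independent. With the preset correlation the p-values of the snoRNA list can therefore be too small in every comparison. The last fold was fitted against 0 counts in both controls and is no bound. The snoRNA list call was lost without 96 h replicate 1 (adjusted p = 0.0713). The structural list ranked higher (adjusted p = 0.0221; adjusted p = 0.207 with an estimated correlation; median 0.15), and this call was lost without control replicate 1 (adjusted p = 0.113) and without 96 h replicate 2 (adjusted p = 0.302). edgeR called 0 of 492 sequences with 8 at an unadjusted p under 0.05, DESeq2 0 with 30 and limma-voom 0 with 4. Adjusted over the list alone both lists gave 0 calls. edgeR and limma-voom called 0 classes, with 2 and 3 at an unadjusted p under 0.05, and DESeq2 called 1 of 3.

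For the mean of the 4 times against the control, the snoRNA list ranked higher (adjusted p = 0.0226; median log2 fold change 1.52) and the structural list lower (adjusted p = 0.0137; median -0.12). The adjusted p of both lists was 0.147 with an estimated correlation. Without 72 h replicate 1 the adjusted p was 0.176 for the snoRNA and 0.231 for the structural list. The snoRNA call was lost as well without control replicate 1 (0.257), 48 h replicate 1 (0.0528) or 96 h replicate 1 (0.0636). The structural call was lost without control replicate 2 (0.151) or 24 h replicate 2 (0.116). The 45S fragment from 8731 to 8754 had a log2 fold change of -2.46 (SE 0.96) and did not pass. edgeR called 0 of 492 sequences with 4 at an unadjusted p under 0.05, DESeq2 0 with 21 and limma-voom 0 with 7. In the joint test of any time, edgeR called 0 with 20, DESeq2 0 with 30 and limma-voom 0 with 9. For the mean, edgeR, DESeq2 and limma-voom called 0 classes, with 0, 2 and 0 at an unadjusted p under 0.05. In the joint test DESeq2 called nuclear rRNA, pseudogenes and snoRNA or snRNA, with 5 classes at that level, while edgeR and limma-voom called 0, each with 4. Adjusted over the list alone, both lists gave 0 calls in both tests.

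Between co-culture times the clearest difference was from 24 to 96 h. Antisense fragments of coding genes fell from 7.47% ± 2.21 to 1.29% ± 0.962 of matched counts, intergenic sequences from 8.75% ± 3.52 to 1.44% ± 0.599 and pseudogene sequences from 2.10% ± 0.618 to 0.306% ± 0.0567. The share of 24 nt among matched counts was also lower at 96 h, at 24.9% and 36.8% against 44.2% and 81.4% at 24 h, as it was within nuclear rRNA fragments (31.4% ± 6.76 against 55.3% ± 26.3). The log2 fold changes of the 3 classes were -2.32 (SE 0.75), -2.41 (SE 0.74) and -2.54 (SE 0.83), and edgeR gave each an adjusted p of 0.0158. DESeq2 called 5 classes, these 3 as well as nuclear rRNA and snoRNA or snRNA as higher, and limma-voom called the same 3. Without 24 h replicate 2 the folds lay between -1.43 and -1.11, with adjusted p of 0.304 to 0.312. Without 96 h replicate 1 they were -1.55, -1.86 and -2.23, with adjusted p of at least 0.119. Without 48 h replicate 1 the antisense class alone was lost (adjusted p = 0.0535), and with upper-quartile scaling the folds were -0.61, -0.70 and -0.93 and none was called. From 72 to 96 h edgeR called 0 classes with 3 at an unadjusted p under 0.05, DESeq2 called pseudogenes as lower and nuclear rRNA as higher, and limma-voom called the antisense, intergenic and pseudogene classes as lower. From 24 to 48 and from 48 to 72 h all tools called 0 classes, with 0 at an unadjusted p under 0.05 by edgeR and limma-voom and 1 by DESeq2 in each.

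The structural list ranked higher at 96 than at 24 h (camera, adjusted p = 3.58e-12; adjusted p = 0.0120 with an estimated correlation; median 0.31), a call kept under both correlations, as was that of 24 h against the control. From 24 to 48 h it ranked higher (adjusted p = 0.000190; adjusted p = 0.111 with an estimated correlation; median 0.71), a call lost without 24 h replicate 2 (0.680) or 48 h replicate 1 (0.231). From 72 to 96 h it ranked higher (adjusted p = 1.67e-06; adjusted p = 0.0507 with an estimated correlation) against a median of -0.05, a call lost without 72 h replicate 1 (0.355). From 48 to 72 h it did not pass (adjusted p = 0.314). fry, which asks whether a list moves one way on balance, called no list in any comparison. The snoRNA list did not pass between co-culture times, and adjusted over the list alone both lists gave 0 calls throughout.

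For single sequences between co-culture times edgeR called 0 of 492, with 9 at an unadjusted p under 0.05 from 24 to 48 h, 14 from 48 to 72 h, 32 from 72 to 96 h and 19 from 24 to 96 h. limma-voom called 0, with 37, 31, 21 and 15. DESeq2 called 0, with 18, 20 and 41, except from 72 to 96 h, where it called 3 of 52 at that level. All 3 were 45S fragments higher at 96 h, in rows 864, 2399 and 2531 of the table, with log2 fold changes of 7.38, 8.81 and 8.61 and adjusted p of 0.0489.

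Sequences of 24 nt, the length of the siRNAs that direct DNA methylation, made up 67.4% ± 5.798 (SD, n = 2) of matched counts in uninoculated roots. Their share was 62.8% ± 26.3 at 24 h, 58.0% ± 18.7 at 48 h, 60.5% ± 31.6 at 72 h and 30.9% ± 8.42 at 96 h. Without structural RNA the shares were 75.7% ± 8.49 in uninoculated roots and 30.3% ± 15.5 at 96 h. At 96 h the share of 21 nt was 16.5% ± 4.61 and that of 22 nt 18.6% ± 0.929, against 5.81% ± 1.48 and 7.43% ± 2.21 in uninoculated roots. Within nuclear rRNA fragments the share of 24 nt was 31.4% ± 6.76 at 96 h and 64.4% ± 5.70 in uninoculated roots. Both 96 h libraries lay below both controls in each of these 24 nt shares, without a test. The longest sequences of the table had 25 nt, but 41597 of the 41601 unmatched sequences had 20 to 24 nt. For unmatched sequences 24 nt is therefore in practice the upper limit, and for matched ones it lies near the upper edge. Longer fragments are not in the table. A high share of 24 nt was also found within nuclear rRNA fragments of uninoculated roots (64.4%), so it does not by itself identify siRNAs.

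The unmatched sequences, among which fungal small RNAs would lie, were tested in the same way. Of the 41601, 9115 (21.9%) lay 1 mismatch from the genome, against 0.642% of shuffled sequences, and 12994 (31.2%) lay within 4 mismatches of Arabidopsis rRNA, against 0.339%. The 10 most abundant in co-culture, taken by raw mean count, all occurred in the controls too. Row 1, a sequence of 24 nt that lies 2 mismatches from the 45S unit, had 4981 and 29546 counts in the controls, 13.8% and 15.1% of these libraries. In co-culture it took 2.81% ± 2.49 (SD, n = 8) of the counts, from 0.419 to 8.53%, with a mean of 4530.2 counts and 1414 without 48 h replicate 1. Row 201, a sequence of 18 nt, took 2.16% ± 3.22 (SD, n = 8) in co-culture, from 0.0459 to 9.64%, and 0.0582% and 3.77% in the controls. Its mean of 5707 counts in co-culture was 3296 without 96 h replicate 2, and by mean share it ranked below row 1. Rows 21, 247, 248, 5, 6, 98, 3 and 623 had mean shares of 0.242 to 1.19% in co-culture. Their raw means of 1387 to 2204 counts rested on 48 h replicate 1 or 96 h replicate 2 and were 153 (row 98) to 1044 (row 21) without the larger of these.

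Unmatched sequences found in co-culture and in no control numbered 28021. Of these, 3223 occurred in at least 2 co-culture libraries, 188 in at least 4 and 0 in all 8. They took 8.05% ± 1.65 (SD, n = 2) of all counts at 24 h, 7.996% ± 1.35 at 48 h, 7.75% ± 4.80 at 72 h and 9.87% ± 3.74 at 96 h. In the opposite direction, 5552 of the 13580 unmatched sequences of the controls occurred in no co-culture library. Of 762 tested unmatched sequences, edgeR called 0 in each of the 10 comparisons, with 0 (48 h against the control) to 62 (72 to 96 h) at an unadjusted p under 0.05 and 38.1 by chance. DESeq2 called 2 from 72 to 96 h, row 263 as higher and row 7892 as lower at 96 h, and row 7892 in the joint test, with 1 to 83 at an unadjusted p under 0.05. limma-voom called 0, with 5 to 50.

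The 4 comparisons with the control shared its 2 libraries, so their log2 fold changes were correlated across sequences, which are not independent replicates. The covariance was 1.22 for 24 and 96 h and 4.53 for 24 and 72 h, the lowest and the highest of the 6 pairs. Simulated unchanged groups that shared 2 simulated controls gave 4.62 and 4.63. The simulation drew the controls anew, so it does not show what these 2 control libraries would give. No sequence was called in any pair of comparisons. Replicates correlated across matched sequences with a mean Pearson r of 0.321 (0.154 to 0.640 in 5 pairs), against 0.385 (0.0332 to 0.802) in 40 pairs of libraries from different groups.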

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

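Of the tests in this part, all but the first test of reads assigned between libraries were chosen only after the result was seen, and for that test the prediction had been written before.

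A difference between groups that passed a test drew attention: at 96 h of co-culture the log2 fold change against 24 h was -2.32 for antisense fragments of coding genes, -2.41 for intergenic sequences and -2.54 for pseudogenes, with both 96 h libraries below both 24 h libraries in each class. Thinning every library at random to 3836 matched counts left -2.06 (SE 0.64) as the fold closest to 0. Random thinning keeps the expected class shares, so this shows only that unequal totals were not needed for the folds. Library depth as the number of captured molecules was not tested and stays open. Scaling between libraries may account for the calls but stays open, since upper-quartile scaling gave -0.61 (SE 0.60), -0.70 (SE 0.52) and -0.93 (SE 0.52), each within 2 SE of 0, and leaving out nuclear rRNA ended the calls at -1.44, -1.56 and -1.72, while RLE size factors (-1.89, -1.97 and -2.11) and total counts (-2.52, -2.59 and -2.77) kept all 3. A few sequences with many copies stayed undecided, since counting each sequence once gave folds of -1.01 (SE 0.95), -1.49 (SE 0.95) and -1.20 (SE 0.64) while capping at 10 counts gave -1.82 (SE 0.79), -2.11 (SE 0.74) and -1.76 (SE 0.51). A change in siRNA production during co-culture, and RNA quality or size selection, were not tested and stay open, and the share of 24 nt was lower at 96 than at 24 h among matched counts (30.9% against 62.8%), within nuclear rRNA (31.4% against 55.3%) and among unmatched counts (24.2% against 47.3%).

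In 3 libraries, replicate 1 of 24, 48 and 96 h, the number of sequences per count value fell and rose again to a second mode, at 13 counts in 24 h replicate 1 and 23 in 48 h replicate 1 for the whole table and at 19 for the matched sequences of 96 h replicate 1. The definition was widened from the whole table to matched or unmatched sequences alone after 2 libraries had been found, and the test was then divided in 2. Library depth and time of co-culture are argued against, since 3 libraries without the mode had larger totals than the smallest with it, and in 3 groups exactly 1 of the 2 replicates had it. A similar copy number of every captured molecule, as from amplification of few molecules, may account for the 24 h and 48 h libraries, where the modes of matched and unmatched sequences lay within 1.09-fold, and stays open in 96 h replicate 1, the 1 library that was included because its matched sequences alone showed the mode, which leaves nothing to test. No biological explanation beyond time was tested.

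Sequences without a match to Arabidopsis took 89.4% and 83.2% of the counts of the uninoculated controls. Single-base errors in reads of plant RNA are argued against as the main source, since at most 5.49% of the unmatched counts lay 1 mismatch from the genome. Reads assigned from co-culture libraries stay open: the controls held 8.09% and 30.7% of their unmatched counts in sequences above every co-culture library, and the second test gave them summed excess shares of 14.5% and 6.26%, so that no bound set in either test was met by both controls. The first test compares raw counts, and 48 h replicate 1 held 833922 against 36106 and 195390 in the controls, so totals limit it. The same excess of each co-culture library over the other co-culture libraries ran from 4.61% to 43.7%. Both control values lie in that range, so the second test cannot decide. rRNA of another organism may be the source of a part, since at least 42.8% of the unmatched counts of each control lay within 4 mismatches of plant rRNA. Row 1 alone, 2 mismatches from the 45S unit, held 13.8% and 15.1% of all counts of the controls. Of the distinct unmatched sequences of all libraries 31.2% lay within 4 mismatches, against 0.339% of shuffled sequences. Which organism stays open, since no fungal or bacterial genome was used here, and no other biological explanation was tested.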

How the results depend on the processing

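Tests named here as total counts, upper-quartile scaling, RLE size factors, DESeq2, limma-voom, no filter, replicate block, only the groups compared, structural RNA, 1 mismatch and single libraries left out were chosen before the data were examined, as were a stricter filter, a minimum fold, an estimated correlation and fry, each for some of the results on matched sequences, named sequences, lists and shares. Their use on classes and unmatched sequences was chosen afterwards, as were locus sums, the fit without the 72 h libraries, distinct sequences, capping, thinning and leaving out nuclear rRNA. Of 1627 alternative values, the counts of called matched sequences were the same in 228 and moved in 5, those of unmatched sequences in 157 and 3, those of classes in 190 and 58, and those of lists in 88 and 38. Group shares were the same in 36 and moved in 9. For the named sequences 599 of 600 were the same and 1 passed, the 45S fragment from 8731 to 8754 at 72 h with total counts; 57 changed sign with neither value called. The 3 falls from 24 to 96 h kept their direction in all 25 alternatives and their call in 14, 15 and 16, with adjusted p from 0.000765 to 0.645. For all changes below the cause was not tested, except that fewer libraries or classes were fitted where these were left out. Depth limits the rare classes: 3 counts were 0.0782% of the matched counts of control replicate 1.

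Matched sequences called were 1 from 72 to 96 h and 1 at any time with RLE size factors; 1 at 72 h and 1 from 72 to 96 h with total counts only; and 3 from 72 to 96 h with DESeq2, instead of 0. Unmatched sequences called were 4 at any time with total counts only, and 2 from 72 to 96 h and 1 at any time with DESeq2, instead of 0.

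Classes called, instead of 3 from 24 to 96 h and 0 elsewhere, were as follows. RLE size factors gave 1 at 24 h and 5 from 24 to 96 h. Total counts only gave 3 at 24 h, 2 at 72 h, 5 from 72 to 96 h, 7 from 24 to 96 h and 2 at any time. DESeq2 gave 1 each at 24, 72 and 96 h, 2 from 72 to 96 h, 5 from 24 to 96 h and 3 at any time. limma-voom gave 3 from 72 to 96 h, and no filter gave 1 at 96 h. Only the groups compared gave 2 at 24 h, 1 at 96 h, 1 from 24 to 48 h and 1 from 24 to 96 h. From 24 to 96 h, 0 were called with upper-quartile scaling, unmatched sequences scaled with the plant classes, 1 mismatch allowed, without nuclear rRNA, distinct sequences or counts capped at 10. Without structural RNA 1 was called from 72 to 96 h and 1 from 24 to 96 h. Without nuclear rRNA 1 was called at 96 h and 1 at any time, and with thinned counts 1 at 96 h, 3 from 72 to 96 h and 1 at any time.

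The counts gave no consistent sign that replicate numbers pair the libraries: correlations of replicate differences ran from -0.355 to 0.442 in 10 pairs of groups. They were over 0.1 in 2 pairs, 24 with 48 h (0.442) and the control with 96 h (0.353). All 3 libraries with a second mode in their counts were replicate 1, and the labels do not say whether the replicate numbers were prepared apart, so this is not settled. With a replicate block 3 classes were called from 72 to 96 h instead of 0.

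The matched share without structural RNA was 2.34% in controls, 28.04% at 24 h, 54.9% at 72 h and 2.52% at 96 h. Over distinct sequences it was 22.1% in controls and 19.96% at 96 h, and with 1 mismatch allowed 18.8% at 96 h. The share of 24 nt in controls was 75.7% without structural RNA and 52.5% over distinct sequences.

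Lists called with an estimated correlation were 0 at 48, 72 and 96 h, for the mean, from 24 to 48 h and from 72 to 96 h. fry called 0 at every time, for the mean and in each step between times. The sign of the structural list was opposite by fry at 48 h (adjusted p = 0.521), 72 h (0.936) and 96 h (0.788), for the mean (0.990) and from 72 to 96 h (0.728), and at 72 h without 72 h replicate 1 (0.775). Leaving out 1 library at a time, its adjusted p at 72 h ranged from 4.73e-11 to 0.775.

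With 1 library left out, where a group is left with 1 library assumed to vary like the others, the lists called ranged from 0 to 1 at 24 h, 0 to 1 at 48 h, 0 to 2 at 72 h, 1 to 2 at 96 h, 0 to 2 for the mean, 0 to 1 from 24 to 48 h, 0 to 1 from 48 to 72 h, 0 to 2 from 72 to 96 h and 1 to 2 from 24 to 96 h. The classes called ranged from 0 to 2 at 24 h, 0 to 3 at 72 h, 0 to 2 at 96 h, 0 to 3 for the mean, 0 to 4 at any time, 0 to 1 from 24 to 48 h, 0 to 1 from 48 to 72 h, 0 to 4 from 72 to 96 h and 0 to 6 from 24 to 96 h. Without both 72 h libraries edgeR called 0 matched sequences in the 5 comparisons left.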

Other observations

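The tests of PRIM2 and AGO2 in this part, and the loci named in it, were chosen only after values had been seen.

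Loci were ranked by sequences that matched 1 place. AT4G03380 (chromosome 4, 1485049 to 1490228) gave 493 counts (166 without 72 h replicate 1), of which 97.2% were 24 nt long, and CYP714A2, a gibberellin-modifying cytochrome P450 gene (chromosome 5, 8563800 to 8566812), gave 490, of which 100% were 24 nt long and 135 remained without 72 h replicate 1. AT1G34580 gave 396 counts, 167 without that library, with 2.78% in sense. By contrast DOT1 with 348 counts and PYK10, the root beta-glucosidase gene of the ER bodies, with 250 (173 and 96 without 72 h replicate 1) gave fragments of exons in sense only. An antisense sequence of HR4, a homologue of a mildew resistance gene, (AGATGATGGGCTTAGATGATGGGC, chromosome 3, 18734280 to 18734303, 21 places) had 14 and 66 counts in the controls, 147 and 162 at 24 h, 222 and 102 at 48 h, 1222 and 10 at 72 h and 0 and 7 at 96 h. Its log2 fold change from 24 to 96 h was -5.83 (SE 2.21), with an edgeR adjusted p of 0.643. Summed per locus, 33 loci were tested and edgeR called 0, with at most 3 at an unadjusted p under 0.05, and no other tool was run on these sums.

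The libraries most alike across matched sequences came from different groups: control replicate 2 and 96 h replicate 2 had a Pearson r of 0.802 across sequences, which are not independent replicates. Across unmatched sequences the highest r was 0.784, between control replicate 1 and 24 h replicate 2, and replicates of a group had a mean of 0.262.

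It was asked whether unmatched sequences that might come from the fungus have more sites of near complementarity in the PRIM2 mRNA (1741 nt) than in other transcripts. Sequences of 20 to 24 nt in no control and in at least 2 co-culture libraries numbered 3223. Sites were scored without gaps, by a penalty for each mismatch and a lower one for each G:U pair, both doubled in the 5' part of the small RNA. PRIM2 had 1 site with a penalty of at most 4, for row 7642 (20 nt, penalty 3.5, mRNA 1254 to 1273), which had 54 counts in 48 h replicate 1 and 5 in 96 h replicate 2. Of 200 transcripts of like length, 27 had as many sites, a share of 0.139 with PRIM2 itself counted. No excess was shown, and with a 95th percentile of 1 site in the other transcripts the counts are too coarse to argue for or against one. At a penalty of at most 3 PRIM2 had 0 sites, and no single small RNA was tested. The small RNA named in the title was not identified here.

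AGO2 (chromosome 1, 11181504 to 11185396), the target of miR403, gave 142 sequences that matched 1 place, a part of those counted for the silencing machinery, with 616 counts (391 without 96 h replicate 2) from both strands, 39.6% of the counts in antisense. No sequence lay inside an intron, where 10.6 of all 142 would by length. The sense ones can be pieces of the mRNA itself, as can the 2 sense sequences found across an exon junction. Only the antisense ones bear on a second strand, and the number expected inside introns was not computed for them alone. Double-stranded RNA made from the spliced mRNA is a candidate explanation, which predicts 0.619 antisense sequences across an exon junction among the 51 antisense ones, and 1 was found. It rests on that 1 sequence. Among 25 loci with at least 100 counts, mainly in exons, 8 had a higher antisense share. Lengths of 23 nt (32.8%) and 24 nt (35.9%) were more frequent than 22 nt (16.4%).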
